A study of Danio rerio with 6 samples.

How the data were processed

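The series measured RNA in 6 libraries from 3 zebrafish ALL tumours, each sorted into SP and nonSP cells. Per the labels' protocols, tumours were removed, cells were sorted by flow cytometry, RNA was extracted with Trizol and libraries were made with a standard Illumina protocol. The authors deposited raw counts per gene, 1 table per library, with 29095 gene symbols in each. Per the submitters' processing notes the tools were STAR 2.5.1b, Cufflinks 2.2.1, featureCounts 1.28.1, DESeq 1.30.0 and edgeR 3.20.7 with genome build GRCz10. The role of each tool, the annotation release and the strand setting are not given in the sources used here. Overlapping and antisense genes cannot be separated without the strand setting, and reads of near-identical copies, such as heat-shock and ribosomal genes, may be split between them. Gene symbols were used as deposited, and no coordinates or gene lengths of the authors' build were used here.

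Groups and tumour numbers were taken from the sample titles. Both fractions with a tumour number come from that tumour, since the design text describes a comparison of fractions in 3 tumours. Deviations of the log2 CPM from the group means correlated across genes at 0.753, 0.839 and 0.818 within tumours 1404, 1279 and 1314, and at -0.274 to -0.485 between tumours. The first and second principal components of the 1000 most variable genes held 63.8% and 27.3% of the variance and separated the tumours, and the component that separated the fractions held 6.0%. Tumour was a block in the model, a choice made from the design text before the data were examined, along with the samples, tests, gene lists and most of the other settings. Whether the authors' own model held such a block is not given in the sources used here. The fit without the block is an alternative, and it ends all calls of edgeR. No pair of libraries agreed within sampling noise (chi-square per degree of freedom from 332 to 1150 over genes), so each was counted as 1 sample.

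Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group (minimum count 10, minimum total 15), which left 15770 genes holding at least 99.81% of the counts of each library. TMM factors were 1.206, 1.441 and 1.757 in SP and 0.683, 0.587 and 0.817 in nonSP (tumours 1404, 1279 and 1314). The model was fitted with glmQLFit (robust) and tested with glmQLFTest, and p-values were adjusted by Benjamini-Hochberg over tested genes at 0.05. The common biological coefficient of variation was 0.353 and the prior degrees of freedom 23.2. The SE of a log2 fold change was its size divided by the square root of F. It draws largely on the spread pooled over genes, so it is not the spread of a gene's ratios between tumours. Log2 ratios per tumour used log2 CPM with a prior count of 2, and CPM were scaled by TMM. Totals ranged from 30213658 to 62398607 counts, and genes near the filter carry the most counting error.

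Of 29 gene lists written before the data were examined, 28 had at least 5 tested members. These were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. None of the lists passed fry's directional test at an adjusted p of 0.05, the lowest being 0.0688 for Wnt signal transduction, fibroblast and ribosomal protein genes. Ribosomal, mitochondrial and oxidative phosphorylation genes were found by symbol pattern. Lists of 11 other cell types were included because a sort gate can hold them.

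Genes named in the text follow a rule fixed in advance. It takes the 14 rising and 14 falling genes with the highest absolute log2 fold change among those past the threshold, with the same direction in all 3 tumours, an average log2 CPM of at least 3 and a symbol that is not a clone or locus name. It adds up to 4 members of each list with the lowest p, of which the text names those that fit each paragraph, and a gene that this part takes is not reported here. It always takes abcg2a, abcb4, abcb5, axin2, lef1, tcf7, ctnnb1, myca, lck, rag2, cd79a and mki67. Genes named only in the closing section, such as lineage markers and collagens, were chosen after values were seen, except the odorant receptor family, which was chosen before.

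Other settings chosen in advance were DESeq2 1.42.0, limma voom with sample quality weights, RLE and upper-quartile factors, no filter, a stricter filter (10 counts in at least 3 samples and an average log2 CPM of 3), each tumour left out, no block, a 2-fold minimum and an adjusted p of 0.1. Library totals without factors, TMM without ribosomal protein and mitochondrial genes, libraries thinned to equal depth, and DESeq2 and limma voom without the block were added after seeing the data. The scripts were tested on simulated data drawn from the real means with 200 genes changed and the tumour block in place. Of genes changed 1.5-fold, 2-fold and 4-fold, 0%, 3.08% and 66.1% were recovered among 14812 tested, and 1 of 44 calls was an unchanged gene. An adjusted p depends on how many genes change, and the data gave 3530 calls. These percents therefore do not give the recovery in the data. With no gene changed, 0 of 14794 genes and 0 lists were called. Simulated genes were drawn independently of each other, so this does not show how often lists of correlated genes would be called.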

Results

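RNA was sequenced from acute lymphoblastic leukaemia (ALL), a cancer of immature lymphocytes, in zebrafish of the clonal strain CG2. Cells of 3 tumours, numbered 1404, 1279 and 1314, were sorted into 2 fractions. The side population (SP) is by convention the fraction that pumps a DNA-binding dye out of the cell, and the non-side population (nonSP) is the fraction that retains it. Each tumour gave 1 library per fraction, so that 6 libraries form 3 pairs, with n = 3 in each fraction. The comparison asks which genes differ between the fractions of a tumour, and the title of the series names the Wnt pathway among them. Total counts per library were 55981608, 45121124 and 54591407 in SP and 62398607, 30213658 and 55521873 in nonSP, for tumours 1404, 1279 and 1314 in that order, which is kept below. The values are raw counts per gene. SP libraries held counts on 22157, 20670 and 21448 genes, against 20713, 17414 and 19547 in nonSP. Of 29095 genes listed, 15770 had enough counts to be tested. Whether the tumours arose independently of each other is not stated in the sources used here, so p-values concern these 3 pairs alone. The p-values and standard errors (SE) rest largely on a spread pooled over genes (prior degrees of freedom 23.2), more than on a gene's own spread between the pairs.

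The SP fraction differed from the nonSP fraction of the same tumour in 3530 genes, of which 2047 were higher and 1483 lower in SP. Of these, 3464 moved in the same direction in all 3 tumours, which passing a paired test favours. Among all 15770 tested genes 8686 did so. Genes that rose included mpx (myeloperoxidase), irf4b (a transcription factor of the interferon regulatory factor family) and the dye-efflux transporter gene abcg2a. Genes that fell included id2a (an inhibitor of basic helix-loop-helix factors), jun (a subunit of the AP-1 transcription factor) and all 72 ribosomal protein genes tested. The counts are from edgeR's quasi-likelihood test with tumour as a block, at a Benjamini-Hochberg adjusted p below 0.05. Without the tumour block edgeR called 0 genes, with 1251 at an unadjusted p below 0.05. Without the block DESeq2 called 18 higher and 29 lower, and limma voom called 0. The calls therefore concern differences within a tumour. SP counts were spread over more genes, with the 50 most abundant genes taking 36.5%, 36.0% and 36.0% of counts in SP and 50%, 52.4% and 45.8% in nonSP. The scaling set how many genes were called in each direction. Library totals in place of TMM factors moved the median log2 fold change of all tested genes by 1.06, from 0.09 to 1.15, and gave 8015 higher and 277 lower genes (96.7% higher, against 58.0%). Changes below are relative to TMM scaling. With it, abundant genes tended to be lower in SP. Above an average log2 CPM of 7, 69 genes rose and 220 fell (median log2 fold change -0.69), against medians of 0.04 to 0.34 in classes of lower level. Leaving out a tumour gave 1247 higher and 1685 lower genes without 1404, 1396 and 667 without 1279, and 1141 and 708 without 1314.

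The 14 rising genes with the highest fold change, chosen by a rule fixed in advance, were led by mpx and radil. mpx rose by a log2 fold change of 3.33 ± 0.47 (SE, n = 3, as for all values after ± below; edgeR adjusted p = 4.42e-05), or 10.1-fold, with SP to nonSP log2 ratios of 3.73, 2.02 and 3.89. radil, an effector of the small GTPase Rap, rose by 3.30 ± 0.48. irf4b rose by 2.69 ± 0.41, from 18, 420 and 30.4 CPM (counts scaled by library total and TMM factor) in nonSP to 284, 1339 and 167 CPM in SP. mfsd2ab, a lysophospholipid transporter gene, reached 644, 1068 and 293 CPM in SP against 45.1, 467 and 46.6 CPM in nonSP (2.57 ± 0.42). noxo1b, an organiser of NADPH oxidase, rose by 2.78 ± 0.52, and rgs13, a regulator of G protein signalling, by 2.56 ± 0.48. The muscle-associated genes neb (nebulin), ttna (titin) and scn4ab (a sodium channel) rose by 2.93 ± 0.47, 2.77 ± 0.53 and 2.91 ± 0.47. The remaining genes of this group were jakmip2 (2.97 ± 0.51), tmtc1 (2.73 ± 0.47), rnd3a (2.68 ± 0.53), acsl4b (2.66 ± 0.51) and slc6a6a (2.65 ± 0.57). rnd3a had 0 counts in nonSP of tumour 1279 and 56 in SP. Without tumour 1404 the values of acsl4b and slc6a6a were 1.61 and 1.48, and without tumour 1279 that of slc6a6a was 4.06. Among the 2047 rising genes the median log2 ratio was 2.18, 1.14 and 1.81 in the 3 tumours, and among the 1483 falling genes it was -1.40, -1.58 and -1.49.

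The 14 falling genes were led by id2a and fzd9b, a Wnt receptor gene. id2a fell by 3.47 ± 0.46 on the log2 scale (edgeR adjusted p = 3.62e-05), from 458, 318 and 59.17 CPM in nonSP to 92.2, 28.6 and 2.37 CPM in SP. fzd9b fell by 3.45 ± 0.42, or 11-fold, with log2 ratios of -2.62, -3.96 and -3.68. jun had the highest level of this group and fell from 3099, 1340 and 354 CPM to 442, 214 and 64.5 CPM, a log2 fold change of -2.64 ± 0.30 with nearly equal ratios of -2.81, -2.65 and -2.46. ier5l, an immediate early response gene, changed by -3.18 ± 0.43, and pdp1, a pyruvate dehydrogenase phosphatase gene, by -3.07 ± 0.43. nusap1, a mitotic spindle gene, and pole3, a subunit of DNA polymerase epsilon, changed by -2.95 ± 0.41 and -2.57 ± 0.38. depdc5, a subunit of the GATOR1 complex that restrains TORC1, changed by -2.77 ± 0.44. The others were znf668 (-3.07 ± 0.40), prr18 (-3.03 ± 0.41), arglu1b (-2.78 ± 0.42), btbd6b (-2.76 ± 0.43), ankrd37 (-2.67 ± 0.44) and efemp2b (-2.59 ± 0.38). All 28 genes of these groups moved in the same direction in each of the 3 tumours, which the rule required.

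**Figure D1:**
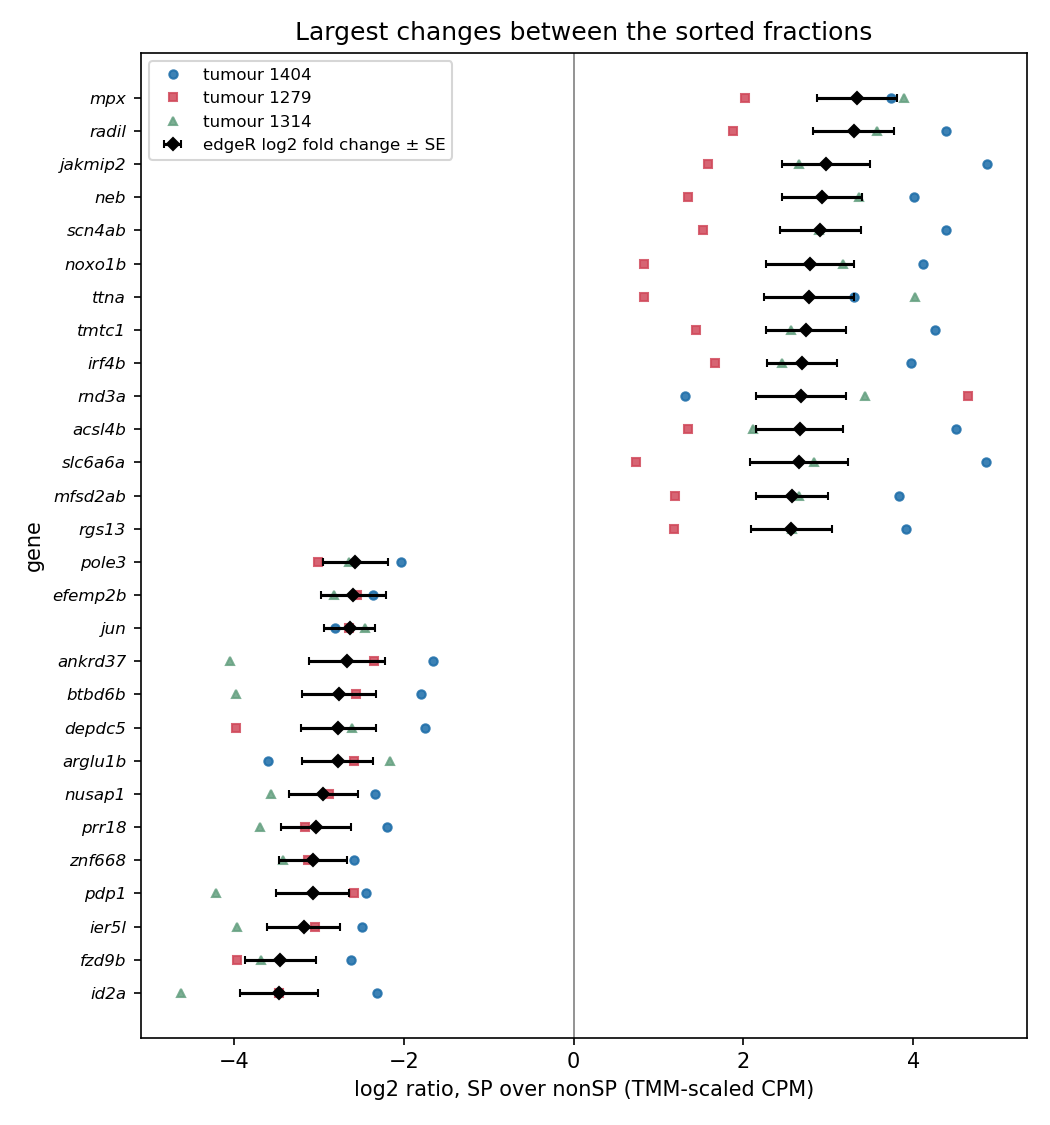
Log2 ratio of SP over nonSP in each of 3 tumours (coloured points, TMM-scaled CPM) and the edgeR log2 fold change with its SE (black diamonds and bars) for the 14 rising and 14 falling genes. In tumour 1279 most rising genes had a smaller ratio than in the other tumours, for example 0.82 for noxo1b against 4.11 and 3.17.

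Members of the Wnt pathway moved in both directions. Of 37 tested genes of Wnt signal transduction, 8 rose and 0 fell over all genes tested, also when adjusted over the list alone. They included ctnnb1, the gene of beta-catenin, at 1.55 ± 0.44 (edgeR adjusted p = 0.0149, ratios 2.90, 0.63 and 1.16), nfatc1 at 2.51 ± 0.48, tle3a at 1.41 ± 0.39 and bcl9l at 1.38 ± 0.38. nfatc1 is a transcription factor of the calcium branch, tle3a a corepressor and bcl9l a coactivator of beta-catenin. The list was higher in SP by camera (adjusted p = 0.0178, median log2 fold change 0.64), a call that was lost with an adjusted p = 0.842 with an estimated correlation and 0.0588 with the stricter filter. With RLE scaling 7 of its genes rose and 1 fell, and with library totals 31 rose and 0 fell. Of 21 Wnt ligand and receptor genes, 2 rose and 4 fell (3 and 5 when adjusted over the list alone, and 9 and 1 with library totals), among them fzd9b, wnt11 (-2.28 ± 0.55), the co-receptor gene lrp6 (-1.55 ± 0.40) and porcn, needed for Wnt secretion (2.22 ± 0.66). Its camera adjusted p was 0.616, and its median of 0.25, mean of -0.06 and downward test differed in sign. Of 20 Wnt target genes, 2 rose and 1 fell, with the same counts when adjusted over the list alone (2 and 2 with upper-quartile scaling, and 9 and 1 with library totals). The camera adjusted p of the targets was 0.855, with a median of 0.04, a mean of 0.18 and a downward test. The Wnt target that fell was jun, and those that rose were tnfrsf19 (1.65 ± 0.45) and sfrp1a, a Wnt antagonist with 17, 133 and 26 counts in SP and 0, 4 and 0 in nonSP. The common readout axin2 stood at 0.69 ± 0.53 (edgeR adjusted p = 0.36), with ratios of 2.02, 0.11 and -0.40, and was -0.25 without tumour 1404. tcf7 stood at 0.26 ± 0.39 (edgeR adjusted p = 0.661) and at -0.09 without tumour 1404, and myca at -1.13 ± 0.43 (edgeR adjusted p = 0.0585), with ratios of 0.15, -1.61 and -1.87. myca passed in DESeq2 (-1.21, adjusted p = 0.0284) and limma voom (-1.29, 0.0118), and in edgeR with upper-quartile scaling (0.0456), the stricter filter (0.0423) and tumour 1404 left out (-1.85, 8.75e-05), while it was -0.04 with library totals. With library totals axin2 (1.75, edgeR adjusted p = 0.00437) and tcf7 (1.36, 0.00253) passed. lef1 was counted 9, 2 and 65 times in SP and 8, 0 and 47 times in nonSP, too few to test. Without tumour 1404, ctnnb1 (0.78, adjusted p = 0.123), bcl9l (0.88, 0.106), tle3a (0.98, 0.0524), tnfrsf19 (0.92, 0.156) and porcn (1.93, 0.153) no longer passed in edgeR. Without tumour 1279, lrp6 (-1.10, adjusted p = 0.209) and porcn (2.07, 0.0764) did not pass in edgeR, and without tumour 1314 tle3a (1.42, 0.0716) did not. The calls of wnt11 (-1.23) and lrp6 (-0.47) also ended with library totals.

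Transporters that can export dyes and drugs were in part higher in SP. Of 23 ABC transporter genes tested, 7 rose and 2 fell (9 and 4 when adjusted over the list alone, and 14 and 0 with library totals), and the list did not pass camera (adjusted p = 0.371). abcg2a, whose mammalian counterpart exports the dye used for side population gating, rose by 1.88 ± 0.40 (edgeR adjusted p = 0.00193), from 6.86, 3.16 and 1.08 CPM to 18.7, 10.4 and 6.24 CPM. abcc1 rose by 2.1 ± 0.43 and abcb6a by 1.85 ± 0.48, and abcb9, a lysosomal peptide transporter gene, changed by -1.79 ± 0.37. abcb4 was counted 3, 2 and 18 times in SP and 5, 0 and 4 times in nonSP, and abcb5 21, 0 and 5 times against 8, 0 and 1 times, too few to test either. Of 20 tested genes of haematopoietic stem and progenitor cells, 5 rose and 1 fell (9 and 2 when adjusted over the list alone, and 16 and 0 with library totals). The transcription factor gene tal1 rose by 2.62 ± 0.45, prom1b by 2.18 ± 0.56, fgd5a by 1.71 ± 0.44 and kitb by 2.05 ± 0.56. This list missed the threshold (camera adjusted p = 0.0565, median 1.03, and adjusted p = 0.842 with an estimated correlation), and passed it with DESeq2 (0.0485), limma voom (0.047) and libraries thinned to equal depth (0.0364). Of 27 Notch pathway genes, 11 rose and 4 fell (12 and 4 when adjusted over the list alone, and 19 and 1 with library totals; camera adjusted p = 0.235). The ligand gene jag1a rose by 1.75 ± 0.39, while her6, hes6 and hey1, members of the hairy and enhancer-of-split family, changed by -2.27 ± 0.40, -2.01 ± 0.43 and -1.84 ± 0.45. In edgeR, abcb6a (1.02, adjusted p = 0.0983) and kitb (1.67, 0.0632) did not pass without tumour 1404. Likewise prom1b (1.98, adjusted p = 0.0654), fgd5a (1.57, 0.0883) and hes6 (-1.34, 0.0735) did not pass in edgeR without tumour 1279, nor fgd5a (1.44, 0.0823) and hey1 (-1.26, 0.0821) without tumour 1314. With library totals the calls of abcb9 (-0.72), hes6 (-0.95) and hey1 (-0.77) ended.

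Ribosomal protein genes were lower in SP in each tumour. All 72 tested ribosomal proteins fell, with log2 fold changes from -1.75 to -1.45 and a median of -1.61. rps2 changed by -1.69 ± 0.21 (edgeR adjusted p = 3.62e-05), rps12 by -1.71 ± 0.22 and rpl6 by -1.64 ± 0.21. The symbol pattern that defined the list also caught 12 other genes, 10 of them S6 kinases, of which 0 were called, so the list of 84 held 0 higher and 72 lower genes (1 and 72 when adjusted over the list alone). The list took 31.5%, 32.6% and 35.0% of all counts in SP and 46.6%, 50.4% and 46.4% in nonSP, and its median of -1.59 became -0.52 with library totals. Its camera adjusted p was 2.46e-33, with an adjusted p = 0.842 with an estimated correlation, as for every list called here. Reads of near-identical ribosomal pseudogenes may be split among copies, which leaves single members uncertain. Of 92 oxidative phosphorylation genes, 28 fell and 0 rose (34 and 0 when adjusted over the list alone; camera adjusted p = 4.85e-10, and adjusted p = 0.842 with an estimated correlation), with a median of -0.81 that was 0.25 with library totals, where 13 rose and 0 fell. ndufb2, of complex I, changed by -1.97 ± 0.41 and atp5ia, of ATP synthase, by -1.57 ± 0.36, calls that ended with library totals at -0.90 and -0.50. Their share of all counts was 0.468%, 0.446% and 0.648% in SP and 0.415%, 0.303% and 0.698% in nonSP. Of 13 genes encoded in the mitochondrial genome, 6 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.00398, and 0.842 as an adjusted p with an estimated correlation). Their median was -0.82, and 0.25 with library totals, where 4 rose and 4 fell. mt-co3, mt-co2, mt-co1 and mt-cyb changed by -1.66 ± 0.24, -1.53 ± 0.24, -1.45 ± 0.23 and -1.42 ± 0.27, and without tumour 1279 the list's adjusted p was 0.227. Of 41 ribosome biogenesis genes, 5 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.128, and 0.00809 without tumour 1404). Their median was -0.09, and 0.98 with library totals, where 23 rose. The RNA helicase gene ddx21 changed by -1.32 ± 0.25 and pno1 by -1.54 ± 0.36. Both lost their call with library totals (-0.24 and -0.47), as did ddx21 in edgeR without tumour 1314 (-1.28, adjusted p = 0.0535) and pno1 without tumour 1279 (-1.39, adjusted p = 0.0615).

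**Figure D2:**
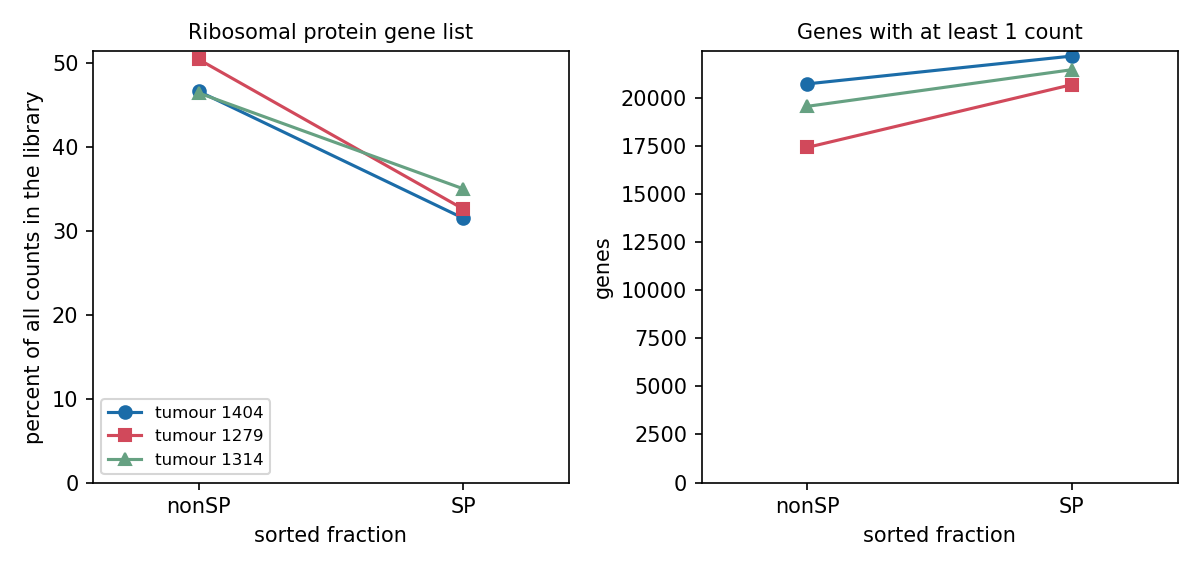
Left, percent of all counts in a library on the ribosomal protein gene list, and right, number of genes with at least 1 count, in the nonSP and SP library of each of 3 tumours (lines join a tumour's fractions). The share was 31.5% to 35.0% in SP and 46.4% to 50.4% in nonSP, and SP libraries held counts on more genes in each tumour.

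Proliferation genes that passed the test were lower in SP, and most members did not pass. Of 43 proliferation genes, 9 fell and 0 rose, also when adjusted over the list alone. Their median was -0.21, and 0.86 with library totals, where 18 rose and 4 fell. aurkb, a kinase of chromosome segregation, fell by 4.31 ± 0.48 (edgeR adjusted p = 2.46e-05), from 254, 184 and 569 counts in nonSP to 24, 16 and 96 in SP. The mitotic cyclin genes ccnb2 and ccnb1 changed by -3.72 ± 0.59 and -2.08 ± 0.44, and nusap1 as given above. mki67, a common proliferation marker, stood at -0.92 ± 0.38 (edgeR adjusted p = 0.0801, lower in 3 of 3 tumours) and at 0.16 with library totals. It passed in DESeq2 (-1, adjusted p = 0.0287), limma voom (-0.97, 0.0341) and edgeR without tumour 1404 (-1.26, 0.00846). Camera called the list lower (adjusted p = 0.00995, and adjusted p = 0.842 with an estimated correlation), but not with the stricter filter (0.393) or without tumour 1314 (0.0549). Of 24 cell cycle arrest genes, 5 rose and 3 fell, also when adjusted over the list alone (17 and 1 with library totals; camera adjusted p = 0.789). foxo1a and mxi1 rose by 1.72 ± 0.40 and 1.77 ± 0.41, and cdkn2c, a CDK inhibitor gene, and btg2 changed by -2.18 ± 0.46 and -1.42 ± 0.33. Of 26 p53 and apoptosis genes, 6 rose and 1 fell (8 and 1 when adjusted over the list alone, and 21 and 0 with library totals), with sesn2 at 2.03 ± 0.42 and tp53inp1 at 1.59 ± 0.44. The camera adjusted p of this list was 0.211, and 0.0458 with library totals. In edgeR without tumour 1404, tp53inp1 did not pass (1.04, adjusted p = 0.0992) and mxi1 stood at 1.17. In edgeR without tumour 1314, tp53inp1 (1.24, adjusted p = 0.116), foxo1a (1.32, 0.067) and btg2 (-1.21, 0.0981) did not pass. With library totals ccnb1 (-1.01) and btg2 (-0.35) did not pass.

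Immediate early and stress genes moved in both directions. Of 40 immediate early and stress genes, 16 rose and 9 fell (20 and 10 when adjusted over the list alone, and 25 and 3 with library totals), and the list did not pass camera (adjusted p = 0.235). Grouped after their values were seen, 7 of its 8 heat-shock members rose and 0 fell (median 2.07), and of the other 32 members 9 rose and 9 fell (median 0.37). This grouping was not tested. hsp70l rose by 2.53 ± 0.36 (edgeR adjusted p = 4.52e-05), reaching 1472, 2130 and 263 CPM in SP against 113, 628 and 59.06 CPM in nonSP, and the chaperone gene hsp90aa1.2 rose by 1.96 ± 0.30. Both have close copies with which reads can be shared, so their values are uncertain. Of 38 glycolysis and hypoxia genes, 8 rose and 3 fell (8 and 9 when adjusted over the list alone; camera adjusted p = 0.781), while 6 rose and 6 fell with RLE scaling and 26 and 1 with library totals. pfkla, a phosphofructokinase gene, rose by 2.25 ± 0.43, the glucose transporter gene slc2a1b by 2.27 ± 0.49 (1.46 without tumour 1404) and hif1ab by 1.63 ± 0.40, while the hypoxia-inducible ankrd37 fell as given above.

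Lymphoid genes moved in both directions with TMM scaling. Of 19 T cell genes, 3 rose and 3 fell (4 and 4 when adjusted over the list alone, and 8 and 0 with library totals; camera adjusted p = 0.855, median -0.24, mean 0.08, test downward). The transcription factor gene runx3 rose by 2.30 ± 0.45, the adaptor gene sla2 by 2.39 ± 0.42 and the chemokine receptor gene ccr9a by 1.27 ± 0.31. rag2, a subunit of the V(D)J recombinase, changed by -1.45 ± 0.38 (edgeR adjusted p = 0.00841, ratios -1.16, -1.60 and -1.60), and the kinase gene lck stood at -0.89 ± 0.39 (edgeR adjusted p = 0.105; 0.0436 in DESeq2, and a value of 0.19 with library totals). Of 15 B cell genes, 3 rose and 1 fell, also when adjusted over the list alone (7 and 0 with library totals; camera adjusted p = 0.616). Besides irf4b these included the receptor gene cd40 (2.0 ± 0.43) and blnk (1.31 ± 0.46, edgeR adjusted p = 0.041), which had 0 counts in both fractions of tumour 1279. cd79a, of the B cell receptor complex, stood at -0.30 ± 0.39 (edgeR adjusted p = 0.621; 0.77 with library totals). Of 28 interferon and antigen presentation genes, 2 rose and 4 fell, also when adjusted over the list alone (17 and 0 with library totals; camera adjusted p = 0.842, median 0.01, mean 0.02, test downward), with gbp1 at -1.56 ± 0.43 and isg15 at -1.26 ± 0.38. Of 18 adhesion and migration genes, 3 rose and 2 fell, also when adjusted over the list alone (10 and 1 with library totals; camera adjusted p = 0.855). The integrin gene itga4 rose by 1.61 ± 0.44, and s1pr1, a receptor of lymphocyte egress, changed by -2.92 ± 0.63. In edgeR without tumour 1404, ccr9a (0.83, adjusted p = 0.108), itga4 (0.84, 0.165), blnk (adjusted p = 0.152) and gbp1 (-1.22, 0.0626) did not pass. Without tumour 1279, rag2 (-1.36, adjusted p = 0.0773), blnk (1.33, 0.0683) and gbp1 (-1.41, 0.0982) did not pass in edgeR. Without tumour 1314, rag2 (-1.38, adjusted p = 0.0878), blnk (1.35, 0.202), isg15 (-1.26, 0.0925) and s1pr1 (-2.04, 0.067) did not pass in edgeR. blnk was also lost in DESeq2 (1.16, adjusted p = 0.0534), in limma voom (1.04, 0.09) and with RLE scaling in edgeR (1.24, 0.0541), and with library totals rag2 (-0.38), gbp1 (-0.49) and isg15 (-0.19) did not pass.

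Markers of other cell types that a tumour sort can hold were measured beside these groups. Rising calls outnumbered falling ones among low-level genes of any kind. At an average log2 CPM of -1 or lower 159 genes rose and 35 fell, and from -1 to 1, 518 rose and 212 fell. sptb (0.397), tfa (0.444) and il10ra (0.361) stood at such a level. From 1 to 3, where col6a1 (2.397) and lum (1.905) stood, 519 rose and 410 fell. Of 10 fibroblast and stromal genes, 5 rose and 0 fell (6 and 0 when adjusted over the list alone), led by col6a1 (collagen VI) at 3.70 ± 0.47 (edgeR adjusted p = 3.62e-05), lum (lumican) at 3.47 ± 0.54, dcn (decorin) at 3.01 ± 0.52 and col12a1a at 3.01 ± 0.55. The list passed camera (adjusted p = 9.14e-05, median 2.52, and adjusted p = 0.842 with an estimated correlation), but not with no filter on low counts (0.0708). Its 27 genes in the files summed to 50.9, 32.7 and 22.4 CPM in SP and 9.27, 8.456 and 9.37 CPM in nonSP. Of 12 endothelial genes, 5 rose and 2 fell, also when adjusted over the list alone (7 and 0 with library totals; camera adjusted p = 0.128), with stab1 at 2.65 ± 0.45, sox7 at 2.39 ± 0.49 and stab2 at 2.37 ± 0.52, besides tal1, which is also on the progenitor list. Of 16 neutrophil genes, 3 rose and 1 fell (4 and 2 when adjusted over the list alone, and 10 and 1 with library totals, with a camera adjusted p = 0.789). Among them mpx was up and cebpa, a myeloid transcription factor gene, stood at -2.02 ± 0.37. Of 13 macrophage genes, 1 rose and 0 fell, also when adjusted over the list alone (7 and 0 with library totals, with a camera adjusted p = 0.789). The gene that rose was il10ra (2.1 ± 0.60, and 1.2 with edgeR adjusted p = 0.204 without tumour 1404). Of 9 erythroid genes, 3 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.128), with sptb at 2.46 ± 0.54. Of 6 thrombocyte genes, 0 rose and 1 fell, also when adjusted over the list alone (2 and 1 with library totals; camera adjusted p = 0.846, median 0.18, mean 0.09, test downward), which was blf (-2.35 ± 0.46). Of 8 muscle genes, 2 rose and 0 fell (4 and 0 when adjusted over the list alone; camera adjusted p = 0.371), neb and casq1a (2.13 ± 0.43). Of 7 epithelial genes, 2 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.424), tp63 (2.35 ± 0.49) and krt18 (2.1 ± 0.49, and 2.45 with edgeR adjusted p = 0.0788 without tumour 1314). Of 5 kidney, liver and pancreas genes, 2 rose and 0 fell (3 and 0 when adjusted over the list alone; camera adjusted p = 0.0868), apoa1b (2.43 ± 0.49) and tfa (2.36 ± 0.56), and this list passed camera without tumour 1404 (adjusted p = 0.0116). With library totals 9 fibroblast and stromal genes and 7 erythroid genes rose and 0 fell. The muscle, epithelial and kidney, liver and pancreas lists then each had 4 higher and 0 lower. Of natural killer and cytotoxic genes, 2 were tested and 0 called, also when adjusted over the list alone, too few for camera.

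**Figure D3:**
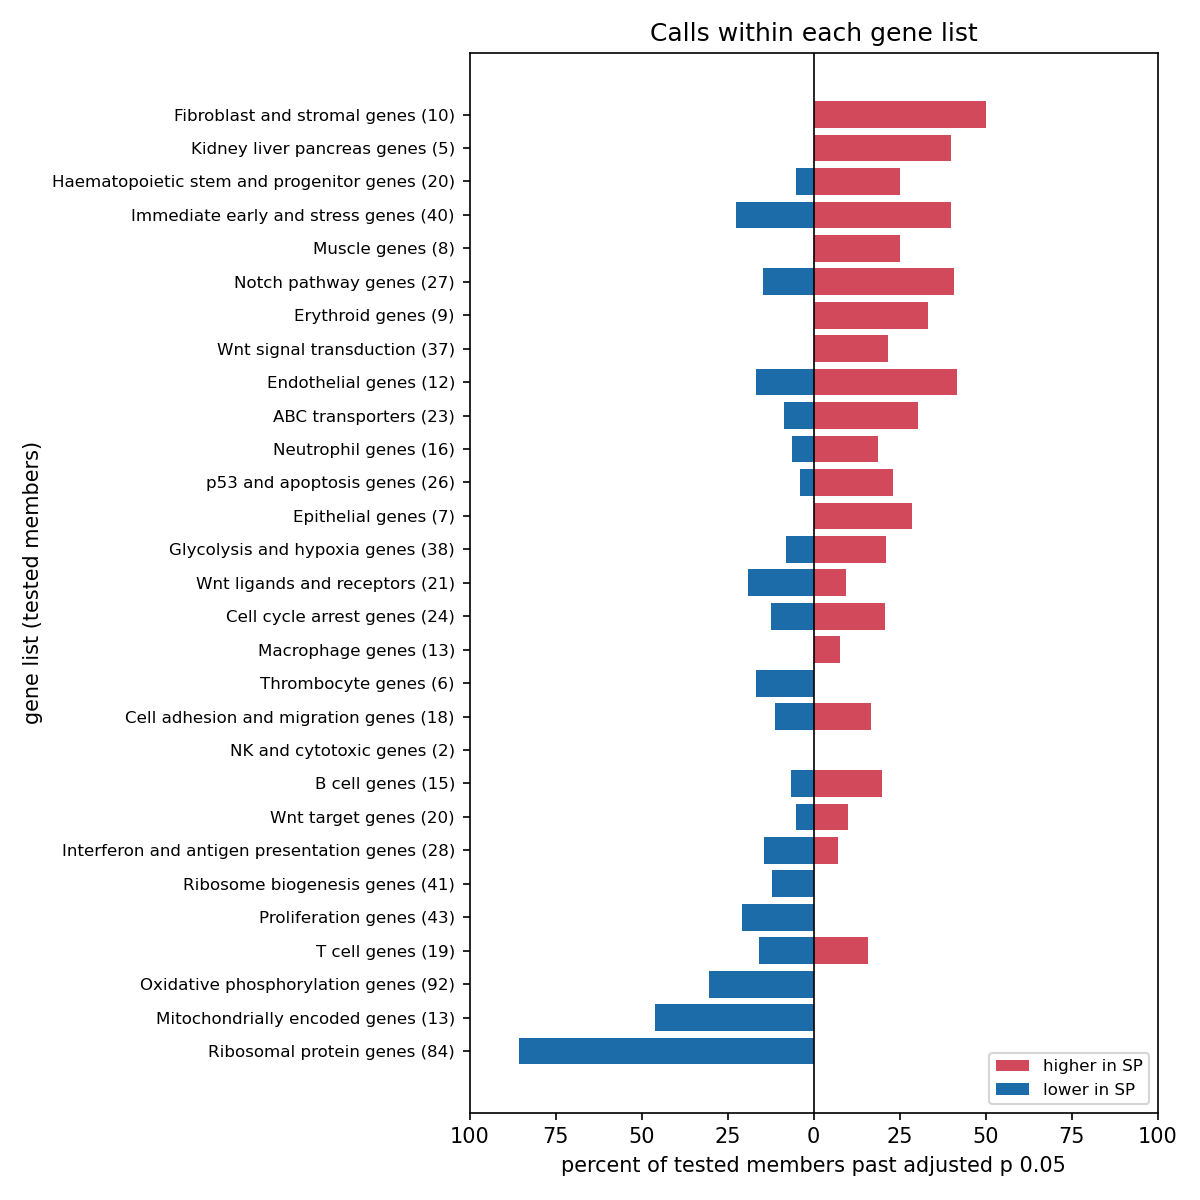
Percent of the tested members of each fixed gene list (number tested in brackets) that were higher (red, right) or lower (blue, left) in SP at an edgeR adjusted p below 0.05 with TMM scaling, lists ordered by their median log2 fold change. Ribosomal protein genes reach furthest to the left (72 of 84) and fibroblast and stromal genes furthest to the right (5 of 10), and with library totals oxidative phosphorylation genes would lie on the right (13 of 92).

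Camera called 6 of 28 lists at an adjusted p below 0.05, and 0 with an estimated correlation. With an estimated correlation camera has few degrees of freedom in 3 pairs. The fibroblast list's unadjusted camera p went from 9.8e-06 to 0.0438, although its estimated correlation of -0.027 lay below the preset 0.01. Loss of every call therefore does not tell the lists apart. The estimated correlations, though from few degrees of freedom, did differ. They were 0.625 for ribosomal protein, 0.959 for mitochondrially encoded, 0.503 for oxidative phosphorylation and 0.156 for proliferation genes. For Wnt signal transduction the estimate was -0.028. Where the estimate lies far above the preset 0.01, the preset camera p-value is too low if the estimate holds. Other divisions of the 6 libraries into 3 and 3, with the tumour block kept, gave from 2 to 8 called lists. These divisions still hold the contrast of SP with nonSP in some tumours, so they do not measure chance. List calls here rest on the preset correlation, while the gene counts within each list rest on edgeR.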

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

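The library-total, reduced TMM and thinned settings, and DESeq2 and limma voom without the block, were chosen after the data had been seen. Against 2047 higher and 1483 lower genes, DESeq2 gave 1999 and 1992 (3441 shared calls), limma voom 2240 and 1842 (3452), RLE scaling 1711 and 1654 (3194), upper-quartile scaling 1828 and 1647 (3310), no filter 2490 and 1334 (3316), TMM without ribosomal protein and mitochondrial genes 2023 and 1512 (3506) and thinning to equal depth 1873 and 1385 (3133). Every shared call had the same direction. The percent higher was 58.0 with TMM, 50.1 in DESeq2 and 96.7 with library totals. With a 2-fold minimum 2044 and 1465 genes passed, and at an adjusted p of 0.1 2877 and 2078. The stricter filter, which tested 6090 genes, gave 1048 and 904. Library totals gave 8015 and 277, and 88 of the 3530 calls took the opposite sign. Without the replicate block edgeR called 0 higher and 0 lower (1251 genes at an unadjusted p below 0.05), limma voom 0 and 0 (1554) and DESeq2 18 and 29 (1643), since tumour differences then enter the residual spread. Leaving out a tumour gave 1141 to 1396 higher and 667 to 1685 lower, with 2 pairs left.

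Of the called genes named in the text, 1 lost its call in DESeq2, limma voom and RLE scaling (blnk), 14 with library totals, 13, 9 and 12 without tumours 1404, 1279 and 1314, and every one in edgeR without the block. The stricter filter still tested 65 of them, and these kept their calls, and s1pr1 without tumour 1404 and sfrp1a after thinning had too few counts to test. Of named genes that were not called, these changed sign: axin2 when a tumour was left out (-0.25 without 1404, up to 1.07), tcf7 likewise (-0.09 without 1404, up to 0.5) and without the block (-0.06), and with library totals, which raised the median of all genes by 1.06, lck (0.19), cd79a (0.77) and mki67 (0.16).

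Camera called 6 lists, 3 with the stricter filter and 0 with an estimated correlation. Under the stricter filter the fibroblast list had too few tested members for camera, so its call was not tested there. Uncalled lists whose test changed direction were, by adjusted p, Wnt ligands and receptors (0.963), T cell (0.963), muscle (0.963), thrombocyte (0.951) and kidney, liver and pancreas genes (0.951) with no filter, and T cell (0.661) and interferon genes (0.885) with the stricter filter. Without the block these were Wnt target (0.978), neutrophil (0.969) and adhesion genes (0.978), and with library totals interferon genes (0.835). Leaving out a tumour turned Wnt target (adjusted p from 0.389 to 0.894 over the 3 fits), T cell (0.909 to 0.973), thrombocyte (0.689 to 0.947), arrest (0.33 to 0.764), glycolysis (0.261 to 0.689) and adhesion genes (0.576 to 0.694) in at least 1 fit. The cause was not tested. Depth limits abcb4, abcb5 and lef1, whose counts were too low to test.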

Other observations

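Several lymphoid genes stood at levels that differed between tumours in both fractions. Tumour 1279 held lck at 237 CPM in SP and 286 CPM in nonSP, rag1 at 214 and 340, gata3 at 88.3 and 65.3 and cd8a at 34.7 and 25.2, while pax5 was at 0.0308 and 0.113 and syk had 0 counts in both. Tumours 1404 and 1314 held pax5 at 23.8 and 16.8 CPM in SP and 25.5 and 32.8 in nonSP, and syk at 27.4 and 12.3 in SP and 32.1 and 11.8 in nonSP, with lck at 4.23 and 13.3 in SP. In background knowledge pax5 and syk mark the B lineage, and lck, gata3 and cd8a the T lineage. Despite these differences irf4b and runx3 were higher in SP of all 3 tumours, runx3 at 77.7, 389 and 79.3 CPM in SP against 7.23, 181 and 15.2 in nonSP. These genes were chosen after their values were seen, and tumour differences were not tested. Sums over the lists fixed in advance did not follow the same division. T cell genes summed to 3330, 2800 and 558 CPM in SP of tumours 1404, 1279 and 1314 (1060, 2160 and 420 in nonSP), where ccr9a alone held 2970, 927 and 215 in SP, and B cell genes to 663, 1470 and 472 CPM (259, 495 and 191 in nonSP), where irf4b held 284, 1339 and 167 in SP.

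In the paragraphs that follow, the tests of scaling, of stromal cells, of odorant receptors without the leading gene or with TMM factors and of the gain of rising genes were chosen after the results had been seen, and the thinning without ribosomal and mitochondrial genes after the first thinning. The others were written down before, except the values by tumour in the transcript length test, which its written rule did not ask for.

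All 72 ribosomal proteins and 28 of 92 oxidative phosphorylation genes were called lower in SP with TMM scaling, and both lists lost their camera call with an estimated correlation (adjusted p = 0.842). Abundant genes were lower in general with this scaling, ribosomal proteins among them. Above an average log2 CPM of 7, 220 genes fell and 69 rose (median -0.69). How far this trend accounts for either list was not tested. For the ribosomal list the median stayed negative with library totals (-0.52). This argues against the choice between TMM and library totals as the source of its direction. Its lower share of counts in SP of each tumour is the same measurement in another form. Neither scaling gives amounts per cell, which were not measured. For oxidative phosphorylation the median was 0.25 with library totals, but these moved the median of all genes from 0.09 to 1.15, so that the value decides nothing about a place below the median gene. Transcript length stays open, as from partly degraded RNA. The length classes were families of gene symbols, not measured lengths. Mitochondrial ribosomal protein genes were among the short ones, so that class is not independent of the lists it was set beside. Outside both lists, 245 short-transcript genes lay -0.51 from the median of all genes (95% bootstrap interval over genes -0.576 to -0.364). The 61 genes with very long transcripts lay at 0.04 (-0.269 to 0.396), under the 0.4 that a trend required. By the rule written before, this alone would have counted against length. The values by tumour 1404, 1279 and 1314 were -0.42, -0.3 and -0.75 for the short and -0.03, -0.32 and 0.42 for the very long. In tumour 1314 these reached the limits on both sides, so that answer was not adopted. A lower content of ribosomal transcripts in SP cells is a hypothesis that also stays open.

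SP libraries held counts on more genes than nonSP libraries of the same tumour. Depth was argued against, since with all libraries thinned to 30213658 counts SP still held at least 1727 more genes in each tumour. Ribosomal protein and mitochondrial genes alone were argued against likewise, since without them, and thinned to a common total, the excess was at least 1184. Other abundant genes were kept in that test. Above an average log2 CPM of 7, 220 genes were lower and 69 higher in SP, ribosomal proteins among them, so the part of other abundant genes stays open. Genomic DNA or unspecific background cannot be told apart from added expression: as a share of all counts the reads on the 138 odorant receptor genes were 3.76, 4.97 and 8.34 times higher in SP (lower limits 3.19, 2.25 and 4.31, for counting error alone), but or101-1 held 577 of the 624 reads in SP of tumour 1404, and without it the ratios were 1.64, 2.68 and 3.2, on 12 to 47 reads per SP library. With TMM factors these ratios became 2.13, 2.03 and 3.88, and 0.926, 1.09 and 1.49 without or101-1 (counting limits from 0.295 to 6.03). That at most 0.733% of the 2047 rising genes gained less than 0.061 CPM on library totals, 10 times the highest mean level of an odorant receptor gene in SP with or101-1 left out, decides nothing for the called genes, since the count filter and the call together ask for about 0.089 CPM, and a wider set of transcripts in SP cells stays open beside background.

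Of 10 fibroblast and stromal genes, 5 were higher in SP and 0 lower, and the list's camera call was lost with an estimated correlation (adjusted p = 0.842) and with no filter (0.0708). Stromal cells in the gate cannot be told apart from expression by other cells. Type I collagen, the most abundant fibroblast transcript in background knowledge, had at most 0.512 times the counts of type VI collagen in SP libraries (196, 50 and 479 against 1056, 784 and 936), which speaks against fibroblasts of that profile. From 172, 6 and 223 counts in nonSP its ratio was 1.27, 5.58 and 2.18 with library totals, where the median of all genes was itself raised, and 0.719, 2.27 and 1.02 with TMM factors, so a rise is not shown, and the profile of the stromal cells was assumed. Expression of col6a1, lum and dcn by cells other than fibroblasts is a hypothesis that was not tested.

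With 6 libraries there are 10 divisions into 3 and 3, too few for a share under 0.05. The real division gave 3530 genes and the highest other 0, so that 1 of 10 gave as many. It gave 6 lists and the highest other 8, and 5 of 10 gave as many. Among the 3 other divisions that also part each tumour's pair, 0 genes and 8, 2 and 6 lists were called. The tumour block was kept in every division. Where a division leaves a tumour's fractions together, the fit rests on the parted tumour, and its contrast is again between SP and nonSP. In the 3 others the real difference enters the residual spread. Neither kind shows what chance would call, so these counts decide nothing about it.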
